A study of Escherichia coli BL21(DE3) with 33 samples.

How the data were processed

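Record-seq was measured in 33 libraries of *Escherichia coli* BL21(DE3) with pFS_0453, recovered from the feces of mice 11 h after the E. coli was given by mouth, from 100 mg of feces each. Groups followed the labels: water and DSS mice at days 5, 9, 15 and 24, with 3 mice each, and vehicle (5) and DNBS (4) mice at day 3. The fits treat all libraries as separate mice; whether a mouse was sampled at more than 1 day is not given in the sources used here.

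The deposited table held counts per gene, as whole numbers without normalization, 1 column per library, with gene lengths in bases. Per the labels, the authors used FastQC, Trimmomatic, Bowtie2, Subread and featureCounts; versions are not given in the sources used here. Coordinates are those of the table, on the BL21(DE3) chromosome. How mates, strands and reads with several matches were counted is not given in the sources used here, so genes with near-identical copies (*rrsD*, *rrsG*, *rrsC*, *rrlD*, *rrlG*, *insL-2*) and genes that overlap another on either strand carry an uncertain assignment. Gene symbols were taken from the table; 3579 of its 4306 matched a symbol of the K-12 MG1655 reference annotation, which was used for names only. Of the 4306 genes 2889 had a count, and 107 were rRNA or tRNA genes. Of nonzero counts 67.2% were even (58.9 to 78.1% per library), with 19396 values of 2 against 1843 of 1; the reason is not given in the sources used here.

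Totals per library ran from 4879 to 81727, so that 3 counts stood for 36.7 to 615 CPM. Intervals and floors cover counting error only, since the counts carry no molecular identifiers. Folds against a group without a count were taken against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of scaled sums is given with its exact (Clopper-Pearson) 95% counting interval. If each spacer was counted 2 times, as the even counts leave possible, these intervals are too narrow and the lowest folds against a floor too high. With the counts halved the intervals were 0.891 to 248 for *lacZ* and 0.305 to 115 for *nanA* at day 5, 4.25 to 1060 for *rne* and 2.58 to 92.9 for *baeR* at day 9, and 6.66 to 1610 for *araH* in DNBS mice.

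Before testing, replicates were compared pairwise by chi-square per degree of freedom over genes with a summed count of at least 10. DNBS replicates 2 and 4 agreed within sampling noise, and their counts were summed into 1 sample, which left 8 samples in the DNBS fit and 32 in the fit of all samples. This was decided after seeing the counts; the planned tests had 9 and 33.

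Library names in the labels end in a number that recurs over groups. Deviations from group means (log2 CPM) correlated at a mean of 0.352 over 38 pairs of libraries with the same number and another treatment, 0.339 over 12 pairs with the same number and treatment, and -0.0398 over 438 pairs with other numbers. As mice of different treatments share it, the number does not mark a mouse. Entered as a block, it lowered the common dispersion of the 24 DSS and water libraries from 0.103 to 0.00740, where 20 shuffles within groups left at least 0.0524. It was added as an alternative after seeing the data, and the main tests, fixed before, leave it out.

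Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 5 and a minimum total of 15, robust quasi-likelihood fits with 1 coefficient per group, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 24 DSS and water libraries were fitted together, giving DSS against water at each day, the mean of the 4 differences, a test that the 4 differences are equal, and a test of days among water mice. DNBS against vehicle was fitted alone. The DNBS effect minus the averaged DSS effect came from the fit of all samples. CPM (counts-per-million) values are TMM-scaled means with SD; log2 fold changes carry SE. Calls were made against a log2 fold change of 0 after scaling, not against the median over all genes, which the text gives where other scalings move it.

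Up to 12 higher and 12 lower genes with the smallest p among those that passed were named per comparison, with up to 4 members of each list that passed. 1 gene picked by this rule is not reported here. The panel *narG*, *hmp*, *norV*, *katG*, *ahpC*, *entC*, *fepA*, *gadA*, *recA*, *nanA*, *eutB*, *tnaA*, *flhD* and *lacZ* was named wherever a gene passed the filter, which *hmp*, *katG*, *ahpC*, *recA*, *nanA*, *tnaA* and *lacZ* did. The comparisons, tests, 35 gene lists, naming rule and alternatives, apart from those listed as added, were fixed before the data were examined. Of 991 listed genes 937 were in the table, 11 by synonym. Lists with at least 3 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), and with an estimated correlation and fry as alternatives. Lists of ribosomal proteins and of translation factors and RNA polymerase, with the rRNA and tRNA share, stood in for reads of other gut bacteria; neither list passed camera in any comparison. With fry, which does not compare a list with other genes, both passed at day 5, at adjusted p = 0.00665 (10 of 45 ribosomal protein genes rose and 3 fell) and 0.0134 (6 of 17 rose and 1 fell), and the rRNA and tRNA share was higher in DSS mice of that day, so reads of other bacteria were not excluded there. The share was also higher in DSS mice at day 24 (15.9 against 13.0%) and lower at days 9 and 15. A list that does not pass camera does not exclude such reads on the other days either.

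Library measures (log10 total count, genes with a count, share of the 10 most counted genes, share of rRNA and tRNA genes) were compared by two-sided exact permutation, or within days by 100000 resamples, with adjustment over 24 tests. Fold changes of 10 pairs of comparisons were correlated across genes against 99 permutations of sample labels, and once more with the library number in the fit and held in place. For each comparison the samples were also split otherwise, in all ways or in up to 100 seeded draws.

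The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 7% and 49% of them in the day 9 comparison (1513 genes), 55% and 87% in the averaged one (1502 genes) and 18% and 70% in the DNBS one (1340 genes), with 0, 3.40 and 1.12% false calls. The simulated libraries were independent, without an effect of the library number, handling shared within groups or an excess of even counts. These rates therefore need not hold for the real data.

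Alternatives were RLE factors, library size only, a minimum count of 10, no filter, DESeq2 1.42.0, limma voom with sample weights, no rRNA and tRNA genes, each replicate left out, only the 6 samples of a day, a replicate block and, for the lists, other set tests. Added after seeing the data were all libraries kept separate, day 5 left out, DSS libraries of day 5 thinned to the depth of the water libraries, halved counts and the library number as a block (in a fit of all 33 libraries for DNBS). Library tables, tests and figures used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9. A *Lactobacillus crispatus* feed was not analysed here, since no sample label names it.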

Results

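The data were Record-seq libraries of *Escherichia coli* BL21(DE3) that had passed through the mouse gut. The cells carried pFS_0453, a plasmid whose CRISPR array takes up pieces of the cell's own RNA as spacers, so that sequenced spacers, counted per gene, record which genes had been transcribed. The E. coli was given by mouth 11 h before each sampling, and plasmid was prepared from 100 mg of feces per mouse. Colitis was induced with dextran sulfate sodium (DSS) in drinking water or with dinitrobenzenesulfonic acid (DNBS), chemicals that injure the colon lining. Mice on water (controls) and on DSS were sampled at days 5, 9, 15 and 24, with 3 mice per group. The DNBS experiment had 5 vehicle and 4 DNBS libraries at day 3. The 33 libraries thus formed 10 groups.

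Total gene counts ran from 4879 to 81727 per library, and 861 to 2489 genes had a count in a library. The water libraries of day 5 were the shallowest, at 4879 to 10864 counts, against 25339 to 35117 in DSS mice of the same day. The ranges at day 9 were 15565 to 30879 in water and 17324 to 27911 in DSS mice, and at day 15 they were 27328 to 59914 and 27139 to 53072. At day 24 water libraries held 20296 to 34810 counts and DSS libraries 28961 to 81727. Vehicle libraries held 37150 to 48527 counts and DNBS libraries 23740 to 76339. A count of 3, the floor used for a gene with no count, stood for 36.7 to 615 CPM (counts-per-million) in single libraries. Over all libraries the genes that took the largest share of counts were the large-subunit rRNA copies *rrlD* (5.01%) and *rrlG* (5.00%), which can share reads, then *raiA*, a ribosome hibernation factor (2.69%), *gatY*, of galactitol breakdown (1.95%), and the chaperone gene *dnaK* (1.33%). DNBS replicates 2 and 4 differed by no more than sampling noise (chi-square per degree of freedom 0.879, p = 0.997, against 1.18 to 3.83 for the other pairs of the group). Their counts were summed and counted as 1 sample, so that DNBS stood at n = 3 against 5 vehicle samples. Pairs of libraries from different groups went as low as 1.23, so a low value does not show that 2 libraries come from 1 mouse. Libraries of different groups that carry the same second number in their library name deviated from their group means together, at correlations of 0.139 to 0.565 in 50 of 50 pairs, against -0.431 to 0.194 in the 438 pairs with other numbers. In the 24 DSS and water libraries 949 of 1613 genes differed by this number, and 0 to 6 did when the numbers were shuffled within groups. What the number stands for is not given in the sources used here. It was not balanced between treatments: number 5 was carried by replicate 2 of each group of water mice and by 1 DSS library. In *yjiM* these water libraries had 3282, 332, 488 and 566 CPM at days 5, 9, 15 and 24, above the other water libraries of each day. Tests of DSS against water can thus carry part of an effect of the number. The tests below do not include it, and each comparison says which calls changed once it was added to the fit, a step taken after the data were seen.

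**Figure D1:**
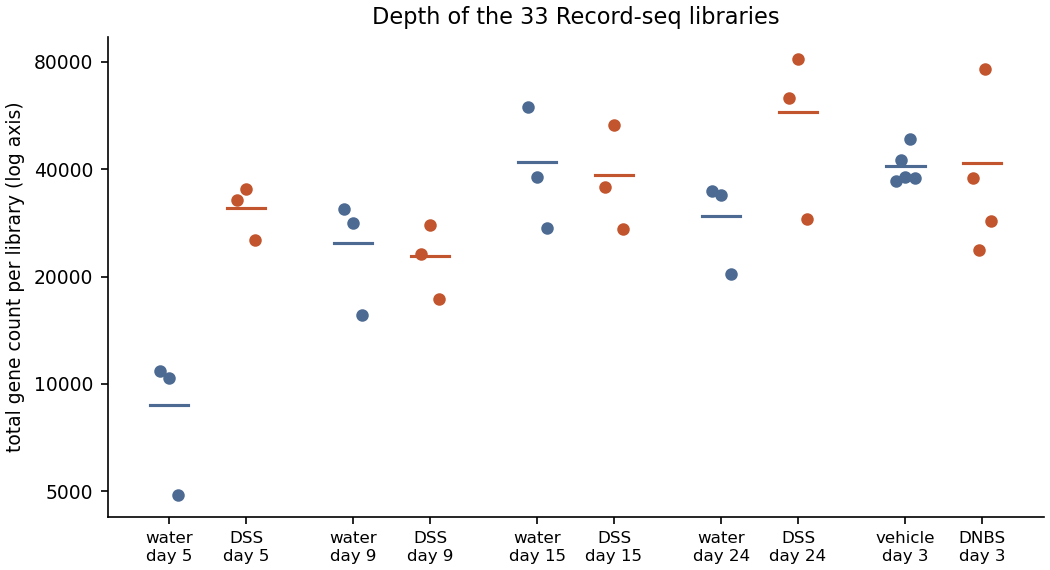
Total gene count per library on a log axis, 1 point per library and a bar at each group's mean. The 3 water libraries of day 5 lie between 4879 and 10864 counts, under all other libraries.

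DSS against water at day 5 asked how E. coli gene expression in the gut differed between mice with DSS colitis and healthy mice. *aspA*, *tnaA*, *gatC* and *dnaK* gave more spacers in DSS than in water mice. *aspA*, which encodes aspartate ammonia-lyase (4273971 to 4275407 on the BL21(DE3) chromosome), rose from 6336 ± 1416 to 14456 ± 1314 CPM (SD, n = 3 each; log2 fold change 1.18 ± 0.15, SE; adjusted p = 8.78e-07). *tnaA*, the tryptophanase that makes indole (3777520 to 3778935), rose from 7496 ± 1885 to 15105 ± 635 CPM (adjusted p = 8.01e-05). *gatC*, part of the galactitol transporter (2070720 to 2072075), rose from 1120 ± 545 to 4239 ± 927 CPM, and *dnaK*, the main heat shock chaperone (12161 to 14077), from 8439 ± 2662 to 17060 ± 1326 CPM (adjusted p = 6.45e-05 for both). In all 4 genes each DSS library lay above each water library.

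Other genes higher at day 5 were *cpxP*, a periplasmic protein of the envelope stress response, at 1355 ± 57.1 against 4020 ± 772 CPM, and *rnr*, encoding RNase R, at 827 ± 263 against 3141 ± 969 CPM. *clpA*, an ATPase that feeds proteins to the ClpP protease, rose by a log2 fold change of 3.38 ± 0.59. *hslJ*, a heat-inducible lipoprotein gene, rose by 2.98 ± 0.53, *narP*, a regulator that answers to nitrate and nitrite, by 2.82 ± 0.51 and *dcrB* by 2.13 ± 0.41. *trxA*, encoding thioredoxin, had no count in water mice and was at least 7.62-fold higher in DSS mice, taking a floor of 3 counts over the group. The rRNA copy *rrsD* rose by 0.87 ± 0.16, but reads of near-identical rRNA copies cannot be assigned with certainty. Among the genes that fell, *yshB*, encoding a small protein, went from 13802 ± 4579 to 5252 ± 610 CPM. *xseA*, an exonuclease subunit, changed by a log2 fold change of -2.68 ± 0.51, *queD*, of queuosine synthesis, by -3.11 ± 0.61 and *bamC*, of outer membrane assembly, by -2.28 ± 0.52. *rpmF*, a ribosomal protein gene, changed by -2.78 ± 0.65 and *mdoH*, of glucan synthesis, by -2.69 ± 0.63. *npr*, which encodes a phosphocarrier protein, had no count in DSS mice and was at least 11.4-fold lower. *btuC* (cobalamin uptake), *ucpA*, *yjiM*, *ychJ* and *ykgJ* were the remaining lower genes of the naming rule, with log2 fold changes of -3.62 to -2.48. In each of these 12 lower genes water mice of day 5 stood above water mice of later days (adjusted p under 0.05), and the difference of DSS mice of day 5 from those later water mice did not pass. Of the higher genes named so far, DSS mice of day 5 stood above later water mice in *aspA*, *tnaA*, *gatC*, *rnr*, *clpA*, *hslJ* and *narP*, while *dnaK* (log2 difference 0.34, adjusted p = 0.0502), *cpxP*, *dcrB*, *trxA* and *rrsD* did not pass. In all of them but *narP* water mice of day 5 stood under later water mice.

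In the heat shock list, 16 of 21 members were measured at day 5, of which 6 rose and 1 fell (10 and 1 adjusted over the list alone). The list passed camera at adjusted p = 0.0305, and had adjusted p = 0.632 with an estimated correlation. *dnaK*, *clpA* and *htpG* (2.72 ± 0.71) rose, while *hslU*, part of a heat shock protease, changed by -2.40 ± 0.65. *ibpA* (1.10), *ibpB* (1.26) and *rpoH* (1.08), picked out after their values were seen, rose as well. Against later water mice, DSS mice of day 5 were higher in *htpG* (1.71) and *rpoH* (0.83), while *ibpA* (0.07, adjusted p = 0.892) and *ibpB* (0.10, adjusted p = 0.859) did not pass, and in these 2 water mice of day 5 stood under later water mice (-1.03 and -1.16). In the same mice, rRNA and tRNA genes took 18.4 ± 0.772% of counts against 14.5 ± 1.82% in water mice (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The envelope stress list, with 25 members measured, had 8 that rose, among them *cpxP*, *surA* (1.79) and *pspC* (2.52), and 1 that fell, *bamC* (10 and 1 adjusted over the list alone), but camera gave adjusted p = 0.629 (0.673 with an estimated correlation). Of 12 fermentation genes, 3 rose, *pflB* (1.36), *adhE* (1.28) and *ldhA* (1.55), and none fell (4 adjusted over the list alone; camera adjusted p = 0.629, and 0.673 with an estimated correlation). These list members were chosen after their values were seen, except *cpxP* and *bamC*. Of the indicator panel, *recA* (log2 fold change 0.96 ± 0.44, adjusted p = 0.116), *katG* (0.75 ± 0.49), *ahpC* (0.69 ± 0.70) and *hmp* (-0.28 ± 0.54) did not pass. Nor did *lacZ* and *nanA*, each with 2 counts in water mice, at ratios of 5.86 (95% counting interval 1.48 to 50.7) and 2.51 (0.559 to 23.1).

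In total 273 of 1613 genes changed at day 5, 218 higher and 55 lower, or 79.9% higher. In 52 of them a group had no count. The groups did not overlap in 29.3% of tested genes (10% by chance for libraries of equal depth). Depth was unequal at day 5, and depth alone can part the groups. *ydfG*, with 6 counts in water and 6 in DSS mice, stood at 148 to 247 and 71.64 to 81.98 CPM. The 29.3% is thus no measure of a difference between the groups. The split followed the scaling: with TMM the median over all genes was at a log2 fold change of 0.64, with RLE size factors at 0.29 and with library size only at 0.06. RLE gave 87 higher and 73 lower genes, DESeq2 had 49.3% of 142 genes higher, and library size only gave 53 higher and 88 lower. Calls were made against a log2 fold change of 0, not against these medians. Of all 55 lower genes, water mice of day 5 stood above later water mice in 49, and DSS mice of day 5 under them in 1. Of the 218 higher genes, DSS mice of day 5 stood above later water mice in 107, and water mice of day 5 under them in 75. With library size only *aspA* (0.59), *gatC* (1.28) and *dnaK* (0.43) still passed edgeR and *tnaA* (0.42, adjusted p = 0.0780) and *rrsD* did not. Without water replicate 2 the count was 171 and the heat shock list had adjusted p = 0.219; with only the 6 samples of the day 32 genes passed and *dnaK* and *tnaA* did not. The heat shock call was also lost with RLE (adjusted p = 0.663), with library size only (0.706) and with a minimum count of 10 (0.369). With the library number in the fit 401 genes passed, 254 of them among the 273, the named genes kept their calls, *recA* passed as well, and the heat shock list did not (adjusted p = 0.168).

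**Figure D2:**
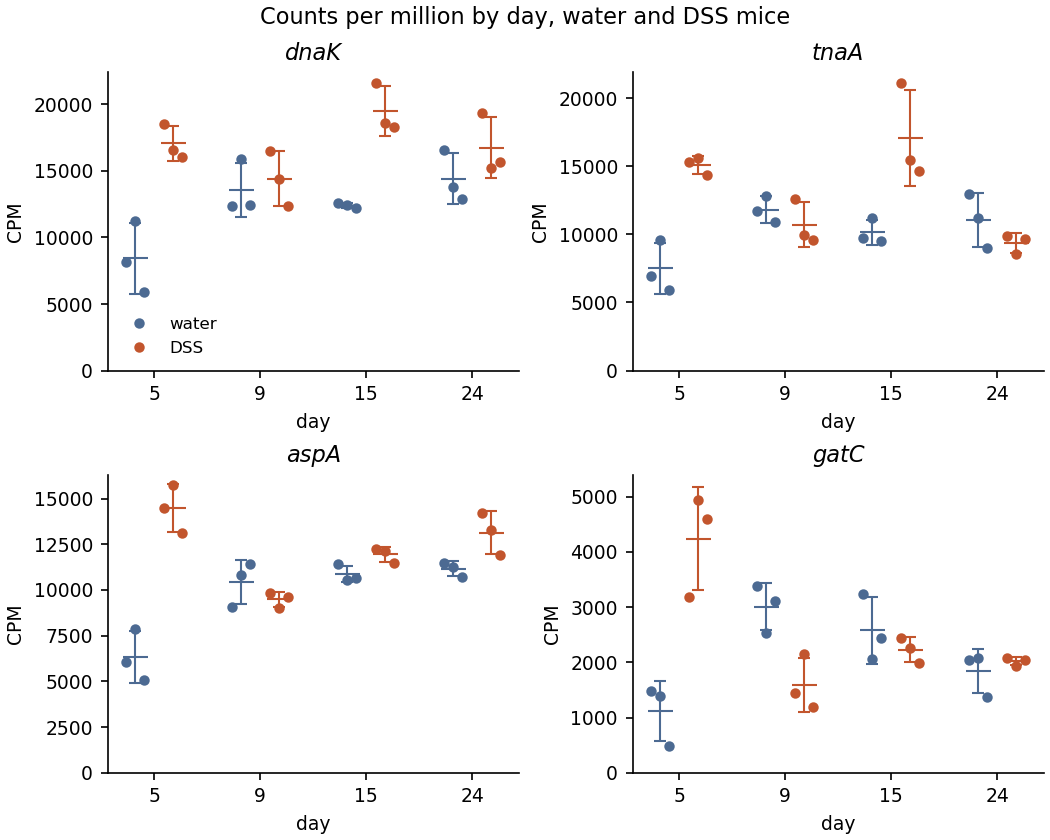
CPM of *dnaK*, *tnaA*, *aspA* and *gatC* by day in water and DSS mice, 1 point per library with the group's mean and SD (n = 3). At day 5 every DSS library lies above every water library, and *gatC* in water mice goes from 1120 CPM at day 5 to 3009 CPM at day 9.

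At day 9, *glpQ*, which breaks down phosphodiesters of glycerol (2240298 to 2241374), rose from 196 ± 45.8 CPM in water to 1547 ± 239 CPM in DSS mice (n = 3 each; log2 fold change 3.00 ± 0.50; adjusted p = 3.48e-04). *fhuA*, the ferrichrome receptor of iron uptake, rose from 143 ± 21.1 to 1094 ± 278 CPM and *ahpC*, the peroxidase subunit of the oxidative stress response, from 134 ± 100 to 610 ± 151 CPM (adjusted p = 0.0159). *cyaA*, adenylate cyclase, rose from 271 ± 37.1 to 1030 ± 332 CPM and *dgsA*, a regulator of glucose uptake also called mlc, from 146 ± 54.7 to 927 ± 169 CPM. *sucA*, a subunit of 2-oxoglutarate dehydrogenase (717270 to 720071), fell from 1875 ± 1499 to 283 ± 126 CPM, and *zipA*, of cell division, from 1822 ± 659 to 492 ± 220 CPM. In each of these genes the 3 DSS libraries lay apart from the 3 water libraries.

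Further genes higher at day 9 were *hrpB*, an RNA helicase (3.29 ± 0.64), *dmsD*, of dimethyl sulfoxide reductase maturation (2.57 ± 0.56), *map*, methionine aminopeptidase (2.14 ± 0.52), *ybiV*, *sseA* and *orf-64* (log2 fold changes of 2.61 to 3.37). *baeR*, an envelope stress regulator, had 3 counts in water and 42 in DSS mice, 14.1-fold higher with a 95% counting interval of 4.50 to 71.0. *ybeL* had no count in water mice and was at least 12.2-fold higher. *rne*, encoding RNase E, had 51 and 2 counts and was 25.4-fold lower (6.67 to 215). Lower genes included *cusB*, of copper efflux (-3.34 ± 0.80), *cysZ*, of sulfate uptake (-2.79 ± 0.66), and *insL-2* (-3.87 ± 0.83), an insertion sequence gene listed at 2 places. Without a count in DSS mice were *proC*, of proline synthesis (at least 13.0-fold lower), *ddlB*, of cell wall synthesis (15.4), *intD* (13.9), *yfiR* (12.1), *acs*, acetyl-CoA synthetase (10.1), and *yiiQ* (7.49). These folds use the mean of the water mice, in which 1 library stood far above the others, and are no bounds for single mice. It was replicate 3 in *ddlB* (1495 against 244 and 291 CPM), *intD* (1246 against 244 and 332) and *yfiR* (1183 against 125 and 279). It was replicate 2 in *proC* (1205 against 125 and 383), *acs* (997 against 139 and 187) and *yiiQ* (623 against 174 and 187). In these 12 lower genes, *sucA* and *zipA* included, water mice of day 9 had the highest mean of the 4 groups of water mice, as in *sucA* with 239, 1875, 445 and 595 CPM at days 5, 9, 15 and 24. Of 12 measured oxidative stress genes, *ahpC* and *dps* (1.85) rose and *sodB* (-0.75) fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.447, and 0.750 with an estimated correlation). Of 15 aerobic respiration genes, the cytochrome oxidase genes *cyoB* (-1.82) and *cyoC* (-1.71) fell and none rose (2 fell adjusted over the list alone; camera adjusted p = 0.909, and 0.965 with an estimated correlation). Of 18 sugar acid and alcohol genes, the galactitol transport gene *gatC* (-0.90) and 1 other fell and none rose (2 fell adjusted over the list alone; camera adjusted p = 0.970, and 0.980 with an estimated correlation); camera and the mean (-0.04) pointed down and the median (0.16) up. *dps*, *sodB*, *cyoB*, *cyoC* and *gatC* were chosen after their values were seen. *katG*, catalase-peroxidase (1.19 ± 0.42, adjusted p = 0.0701), *hmp*, which detoxifies nitric oxide (-1.28 ± 0.47, 0.0787), *recA* (0.89 ± 0.41), *tnaA* (-0.14 ± 0.16), *lacZ* (0.35 ± 0.64) and *nanA* (0.14 ± 0.59) did not pass.

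Altogether 136 of 1613 genes changed at day 9, 53 higher and 83 lower, 16 with a group at no count. The groups did not overlap in 22.4% of tested genes (10% by chance for libraries of equal depth). No gene list passed. DSS mice of day 9 lay nearer to water mice of days 15 and 24 than water mice of day 9 did in 79.5% of the 83 lower genes, 26.4% of the 53 higher genes and 56.5% of all tested genes. Leaving out single libraries gave 52 genes (without water replicate 2), 78 (water replicate 3), 60 (DSS replicate 1) and 39 (DSS replicate 3). With only the 6 samples of the day 41 genes passed, *ahpC* not among them, and limma voom gave 81. Adding the library number gave 133, 82 of them among the 136; *acs* did not pass and *katG* did.

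At day 15, *tnaA* and *dnaK* were again higher in DSS mice: *tnaA* rose from 10165 ± 914 to 17063 ± 3542 CPM (n = 3 each; log2 fold change 0.75 ± 0.16; adjusted p = 0.0177) and *dnaK* from 12392 ± 190 to 19488 ± 1848 CPM (0.65 ± 0.15; adjusted p = 0.0219). *tnaC*, the leader peptide of the *tna* operon, rose with *tnaA* (1.20, chosen after its value was seen). *ydfG*, a dehydrogenase gene, rose from 52.4 ± 18.7 to 449 ± 127 CPM, *rfaF*, of lipopolysaccharide core synthesis, from 52.4 ± 18.7 to 486 ± 217 CPM, and *coaA*, pantothenate kinase, from 176 ± 47.7 to 868 ± 219 CPM. *ilvG*, of branched-chain amino acid synthesis (2.35 ± 0.60), *nrdF*, a ribonucleotide reductase subunit (2.41 ± 0.61), *folM* (2.80 ± 0.64), *yidA*, *ycgG*, the tRNA gene *glyY* and the ribosomal gene *rplV* (2.71 ± 0.71) were higher too. The ribosomal genes *rplM* (-1.59 ± 0.40) and *rplQ* (-1.44 ± 0.38) were lower, as were *ibsB3*, a small toxic peptide gene, *yceA* and *rlmN*. The panel genes *ahpC* (0.90 ± 0.45, adjusted p = 0.288), *nanA*, *recA*, *katG*, *lacZ* and *hmp* (log2 fold changes of -0.64 to -0.03) did not pass.

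At day 15, 40 of 1613 genes changed, 35 higher and 5 lower, and no gene list passed. DSS mice of day 15 lay nearer to water mice of days 9 and 24 than water mice of day 15 did in 60% of the 5 lower genes, 11.4% of the 35 higher genes and 44.0% of all tested genes. The groups did not overlap in 27.0% of tested genes (10% by chance for libraries of equal depth). These calls depended on each library: without 1 of the water replicates 1, 2 and 3 the counts were 0, 1 and 0, and without DSS replicates 1, 2 and 3 they were 0, 9 and 10. None of the 17 named genes that passed did so under all alternatives; limma voom gave 173 genes and no filter on low counts 23. Adding the library number gave 205 genes, 128 higher and 77 lower, with all of the 40 among them.

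At day 24 single genes differed between DSS and water mice and no gene list passed. *srlB*, part of the sorbitol transporter, fell from 944 ± 132 to 164 ± 38.9 CPM (n = 3 each; log2 fold change -2.54 ± 0.51), and *srlD*, sorbitol-6-phosphate dehydrogenase of the same operon, from 876 ± 145 to 151 ± 63.5 CPM (-2.46 ± 0.51; edgeR adjusted p = 0.00298 and 0.00300). *nagB*, which converts glucosamine 6-phosphate, rose from 452 ± 127 to 1652 ± 420 CPM (1.86 ± 0.42; adjusted p = 0.00789). *nagC*, the repressor encoded near it in the *nag* locus, fell from 850 ± 224 to 155 ± 65.3 CPM (-2.48 ± 0.51). *xylH*, of xylose uptake, fell by 2.46 on the log2 scale (SE 0.51). In each of these genes the groups did not overlap.

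The lowest p at day 24 belonged to *ydjM*, an SOS-regulated gene, which fell from 904 ± 243 to 76.6 ± 24.4 CPM (-3.58 ± 0.58; adjusted p = 1.98e-04). *osmB*, an osmotically induced lipoprotein gene (-3.32 ± 0.64), *flgD*, a flagellar hook gene (-3.09 ± 0.62), *murA*, the first enzyme of peptidoglycan synthesis (1172 ± 25.3 against 261 ± 17.0 CPM), and *iscR*, the iron-sulfur cluster regulator (-2.61 ± 0.62), were lower, as were *ves*, *rimN* and *ypfH*. Besides *nagB*, the higher genes were *pflB*, pyruvate formate-lyase (1.34 ± 0.35), *clpB*, a disaggregating chaperone (1.00 ± 0.27), *gcvP*, of glycine cleavage (1.91 ± 0.52), *yeeX* (1.07 ± 0.25) and *inaA* (1.95 ± 0.54). *recA* stood at 1.15 ± 0.34 (adjusted p = 0.0690), which did not pass, and *lacZ*, *tnaA*, *katG*, *hmp*, *ahpC* and *nanA* (-0.25 to 1.27) did not pass either. Of the water groups, that of day 24 had the highest mean CPM of *ydjM*, *srlB*, *srlD*, *nagC*, *murA* and *flgD*.

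In DSS versus water at day 24, 22 of 1613 genes changed, 6 higher and 16 lower. The groups of day 24 did not overlap in 27.0% of tested genes (10% by chance for libraries of equal depth). At this day rRNA and tRNA genes took 15.9 ± 2.65% of counts in DSS and 13.0 ± 0.699% in water mice. The exact permutation p was 0.1, two-sided, the smallest that 3 against 3 allows. In 93.8% of the 16 lower genes, 0% of the 6 higher genes and 35.0% of all tested genes, DSS mice of day 24 lay nearer to water mice of days 9 and 15 than water mice of day 24 did. With library size only, which moved the median over all genes from -0.01 to -0.19, 10.3% of called genes were higher and *gcvP*, *clpB* and *inaA* no longer passed; with DESeq2 44.2% of 43 genes were higher. Without water replicates 1 and 3 the counts were 3 and 13, without DSS replicates 1 and 2 they were 5 and 3, and with only the 6 samples of the day 163 genes passed. Adding the library number gave 24, 17 of them among the 22; *gcvP*, *clpB* and *inaA* did not pass and *recA* did.

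**Figure D3:**
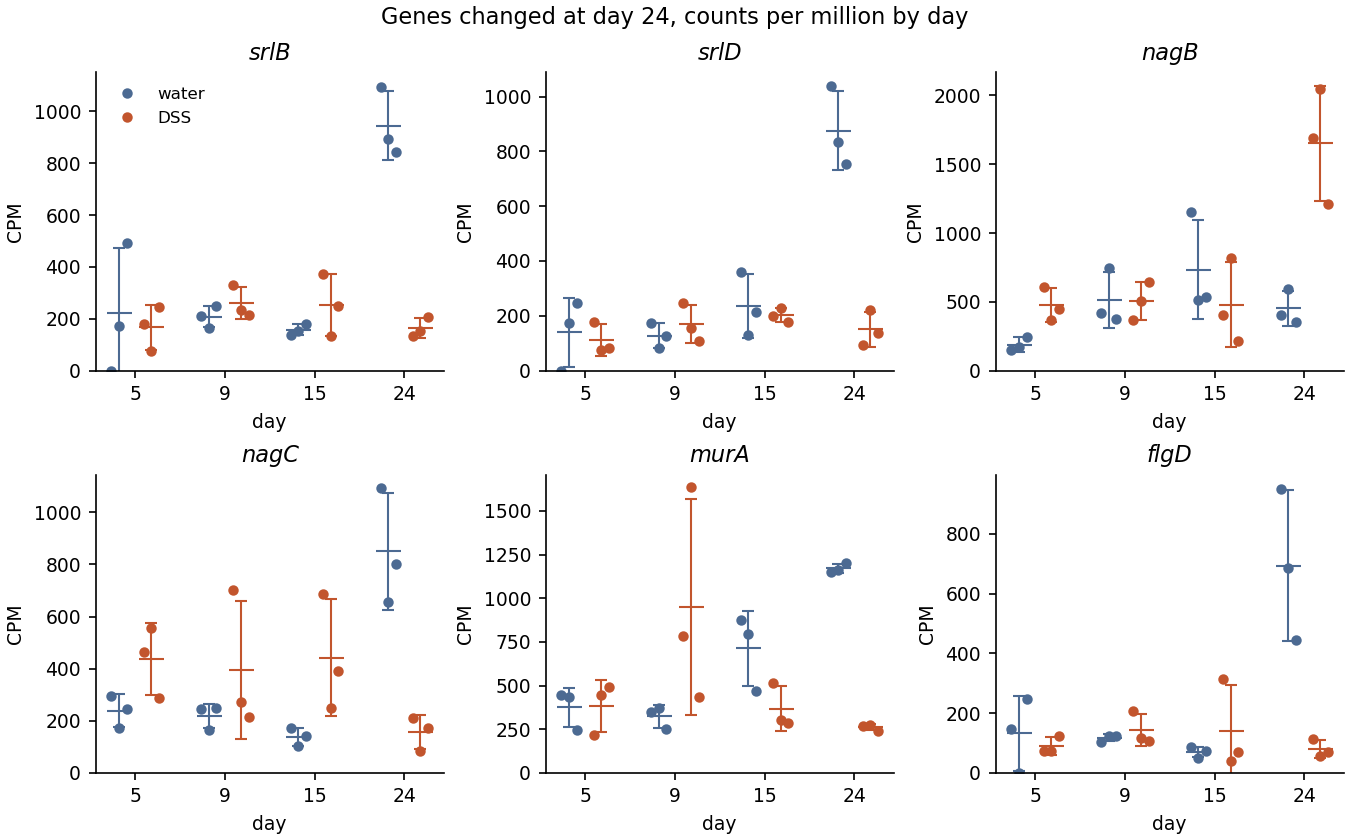
CPM by day of *srlB*, *srlD*, *nagB*, *nagC*, *murA* and *flgD* in water and DSS mice, 1 point per library with mean and SD (n = 3). At day 24 the groups do not overlap in any of the 6 genes, and the water mice stand at 944 CPM of *srlB* against 164 CPM in DSS mice.

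Averaged over the 4 days, with 12 samples per side, the heat shock and nucleotide metabolism lists passed camera, but neither did with an estimated correlation (adjusted p = 0.270 for both), without day 5 (0.226 and 0.118) or with the library number in the fit. *dnaK* rose by a log2 fold change of 0.49 ± 0.08 and was higher in DSS at 4 of 4 days (adjusted p = 1.60e-04). *groL*, the large chaperonin subunit (0.54 ± 0.13), and the small chaperones *ibpB* (0.64 ± 0.15) and *ibpA* (0.51 ± 0.14) were also higher at 4 of 4 days. Such a tally takes no account of the size of a difference. *ibpB* at day 24 stood at 3082 ± 1350 CPM in water and 3129 ± 672 CPM in DSS mice. *ibpA* at day 15 stood at 2402 ± 1014 and 2499 ± 419 CPM. *ahpC* rose by 1.08 ± 0.28 at 4 of 4 days (adjusted p = 0.0150), and *recA*, of DNA repair, by 0.66 ± 0.19 with 3 of 4 days higher (adjusted p = 0.0244). Of nucleotide metabolism, *pyrH*, which makes UDP (1.53 ± 0.35), *purL* (1.91 ± 0.51) and *guaA* (2.16 ± 0.62) of purine synthesis, and *udp*, uridine phosphorylase (2.15 ± 0.63), rose.

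The heat shock list had 7 of 16 measured members higher and 1 lower on average (9 and 1 adjusted over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.270 with an estimated correlation). Nucleotide metabolism had 5 of 18 higher and none lower (8 adjusted over the list alone; adjusted p = 0.0409, and 0.270 with an estimated correlation). Beside these lists, the share of counts in rRNA and tRNA genes was 15.0 ± 2.90% in DSS and 13.5 ± 1.56% in water mice (permutation p = 0.0541 within days, adjusted 0.171). Oxidative stress, with *ahpC* and *dps* higher (4 adjusted over the list alone), did not pass at adjusted p = 0.107 (0.270 with an estimated correlation). Other higher genes were *trxA* (2.29 ± 0.44), *metJ*, the repressor of methionine synthesis (2.08 ± 0.46), *gutM*, an activator of the sorbitol operon (2.91 ± 0.64), *lrhA*, a repressor of motility (0.81 ± 0.17), *narP* (1.05 ± 0.21), *aspA* (0.35 ± 0.07), *smg* and *ygfB*. The rRNA copy *rrsC* was higher as well (2.20 ± 0.47), with the uncertainty of shared reads. *tnaA* was higher on average (0.34 ± 0.08), with DSS above water at 2 days and under it at the other 2. *trxA*, *rrsC*, *metJ*, *gutM*, *purL*, *guaA* and *udp* had no count in water mice of day 5, so that their fitted averages depend on the prior count and are no bounds. Lower were *gshB*, of glutathione synthesis (-1.89 ± 0.36), *yshB* (-0.61 ± 0.11), the ribosomal genes *rplM* (-0.94 ± 0.20) and *rplO* (-2.15 ± 0.55), *hupB*, a DNA-binding protein gene (-0.33 ± 0.09), *prmC*, *yjiM*, *ycdZ*, *yqfB*, *pagB*, *ybl117* and *ibsB3*. *lacZ* (1.00 ± 0.37, adjusted p = 0.0744), *katG* (0.52 ± 0.22, 0.108), *hmp* (-0.30 ± 0.23) and *nanA* (0.22 ± 0.34) did not pass.

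On average 177 genes changed, 120 higher and 57 lower. The median over all genes was 0.19 with TMM, 0.10 with RLE and 0.03 with library size only, and the split was 88 to 75 with RLE and 49 to 87 with library size only, where *aspA*, *tnaA*, *groL*, *ibpA* and *recA* did not pass; DESeq2 had 47.3% higher. Without day 5, 93 genes passed (33 higher, 60 lower), 51 of them shared with the 177, and neither list did. There *dnaK*, *ahpC* and *groL* still passed, while *recA*, *ibpA*, *purL*, *guaA* and *udp* did not, and these are not all the calls that were lost. *aspA*, *narP*, *smg*, *metJ* and *rrsC* also lost their call in at least 1 alternative. Their lowest log2 fold changes over the alternatives were 0.09, 0.48, 0.39, 0.71 and 0.69. In *aspA*, *narP* and *smg* DSS was above water at 3 days and under it at 1. The count was 109 without water replicate 2 of day 15, 113 without water replicate 2 of day 24, 111 without DSS replicate 1 of day 5 and 115 without DSS replicate 1 of day 9. With RLE both lists stood at adjusted p = 0.0505. With the library number in the fit 155 genes passed, 114 of them among the 177, and *udp*, *rplO*, *prmC*, *yjiM*, *ycdZ*, *pagB* and *ibsB3* did not.

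Whether the DSS effect differed between days was tested directly, and 239 of 1613 genes passed. *gatC* had the lowest p (adjusted p = 2.71e-04): its mean went from 1120 CPM in water to 4239 CPM in DSS mice at day 5, and from 3009 to 1591 CPM at day 9. *tnaA* was 7496 against 15105 CPM at day 5, 11825 against 10715 at day 9, 10165 against 17063 at day 15 and 11054 against 9349 at day 24 (adjusted p = 3.52e-04). *lpp*, the main outer membrane lipoprotein gene, stood at 4203 CPM in water and 7796 CPM in DSS mice at day 5, and at 9872 and 6621 CPM at day 9. *aspA*, *yeiH*, *rnr*, *clpA*, *xylH*, *nagC* and *murA* differed too, and so did the rRNA copies *rrsD* and *rrsG*. Of the panel, *tnaA* alone passed; *recA* (adjusted p = 0.0648), *hmp*, *katG*, *ahpC*, *lacZ* and *nanA* did not. The count was 156 without water replicate 1 of day 15, 132 without water replicate 1 of day 24, 132 without DSS replicate 1 of day 15 and 158 without DSS replicate 2 of day 24; limma voom gave 51 genes. Without day 5, *gatC*, *aspA*, *rnr* and *clpA* did not pass. With the library number in the fit 449 genes passed, 197 of them among the 239, and *recA* and *katG* did as well.

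The water mice alone gave the background of change over days, with 399 of 1613 genes differing between days 5, 9, 15 and 24. *yshB* was at 13802 ± 4579 CPM at day 5 and at 4752 to 5245 CPM later (adjusted p = 3.47e-07). *lpp* was at 4203 ± 980 CPM at day 5 and at 8272 to 9872 CPM later. *dnaN*, the sliding clamp of DNA replication, was at 2945 ± 1613 CPM at day 5 and at 525 to 730 CPM later, and *gatA*, of galactitol uptake, at 799 ± 146 CPM against 1473 to 3000 CPM. *dapB*, of lysine and cell wall synthesis, had its highest mean at day 9 (1170 ± 746 CPM) and *ydjM* at day 24 (904 ± 243 CPM). *zraS*, *rpmF*, *ygeV*, *btuC*, *xseA* and the rRNA copy *rrsD* differed as well, as did the panel genes *recA* (adjusted p = 0.00765) and *tnaA* (0.0186), while *nanA*, *ahpC*, *lacZ*, *hmp* and *katG* did not pass. The labels give no handling or sequencing batches, so day and any such batch cannot be told apart. Without day 5, 204 genes passed and *yshB*, *lpp*, *dnaN*, *zraS*, *ygeV*, *xseA* and *tnaA* did not; limma voom gave 58. With the library number in the fit 516 passed, 341 of them among the 399, *lacZ* and *hmp* included.

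DNBS against vehicle at day 3 asked the same of a second colitis model. *mdh*, malate dehydrogenase, rose from 79.7 ± 22.6 CPM in vehicle to 653 ± 190 CPM in DNBS mice (SD, n = 5 and 3; log2 fold change 2.99 ± 0.48; adjusted p = 6.88e-04), and *araH*, of arabinose uptake, from 10.3 ± 23.1 to 367 ± 115 CPM (2 and 69 counts; ratio 39.1, 95% counting interval 10.4 to 329). *nrdG*, which activates the ribonucleotide reductase used without oxygen, rose from 51.0 ± 6.33 to 430 ± 167 CPM (3.04 ± 0.56). *nupC*, a nucleoside transporter, fell from 427 ± 139 to 29.1 ± 26.2 CPM, and *amiA*, an amidase that splits the cell wall at division, from 447 ± 152 to 24.2 ± 42.0 CPM. In each of these genes every DNBS sample lay apart from every vehicle sample.

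Other genes lower in DNBS mice were *cytR*, a repressor of nucleoside uptake (-2.41 ± 0.46), *mraY*, of peptidoglycan synthesis (-3.57 ± 0.70), *yliI*, a sugar dehydrogenase gene (-3.99 ± 0.65), *ydiP*, *ynfD* and *yaiL*. *ybbA*, *pepA* and *menF*, of menaquinone synthesis, had no count in DNBS mice and were at least 14.8-, 13.9- and 11.4-fold lower. Higher were *yiiR* (3.33 ± 0.53), *pmrD*, of polymyxin resistance signalling (2.75 ± 0.52), and *yfeS* (2.91 ± 0.56). *bax* (at least 23.2-fold), *yeaH* (16.7), *ybjI* (15.8), *mqsR*, a toxin gene (14.6), *puuD*, of putrescine breakdown (13.4), and *ybiB* (13.1) had no count in vehicle mice. No panel gene passed: *ahpC* stood at -0.92 ± 0.42 (adjusted p = 0.0946), *nanA* at 0.85 ± 0.45 (0.151), *recA* at 0.34 ± 0.26, *katG* at -0.41 ± 0.33, *tnaA* at 0.14 ± 0.19, *hmp* at -0.29 ± 0.41 and *lacZ* at -0.20 ± 0.40.

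No gene list passed in the DNBS comparison, and the lists with most changed members went both ways. Of 10 measured mucin sugar genes, *nagE*, the N-acetylglucosamine transporter (1.69), *nagB* (1.21) and the sialic acid genes *nanT* (2.32) and *nanS* (2.97) were the 4 that rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.782, and 0.879 with an estimated correlation). Of 19 sugar acid and alcohol genes, 1 rose and 5 fell, among them *srlA* (-2.94), *srlE* (-2.52) and *srlB* (-1.92) of the sorbitol operon (1 and 5 adjusted over the list alone; adjusted p = 0.828, and 0.879 with an estimated correlation). Of 9 zinc, manganese and copper genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.758, and 0.879 with an estimated correlation). Amino acid biosynthesis had 5 of 23 higher, such as *ilvM* (3.51) and *serA* (2.82), and 8 lower, such as *leuC* (-2.40) and *ilvC* (-1.83), with the same counts adjusted over the list alone (adjusted p = 0.828, and 0.879 with an estimated correlation). Of 16 aerobic respiration genes, 3 rose and 4 fell, and *sdhA* (3.59) rose while *sdhB* (-2.27), of the same succinate dehydrogenase, fell (4 and 4 adjusted over the list alone; adjusted p = 0.899, and 0.894 with an estimated correlation). The list members named here were chosen after their values were seen.

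In all, 501 of 1417 genes changed in DNBS mice, 221 higher and 280 lower, 15 of them with a group at no count. The groups did not overlap in 38.4% of tested genes. Without DNBS replicate 3 the count was 157; a minimum count of 10 gave 285 genes and no filter 794. A fit of all 33 libraries with the library number gave 536, 388 of them among the 501; *pepA* did not pass, and *nanA* and *tnaA*, both higher in DNBS mice, did. Vehicle replicate 4 and DNBS replicate 3 each carry a number that no other library has. The block takes these libraries up, so in that fit they do not inform the DNBS effect. DNBS replicates 2 and 4 stood there as separate samples. The rRNA and tRNA share was 12.8 ± 1.33% in vehicle and 8.54 ± 2.00% in DNBS mice, and the 10 most counted genes took 21.5 ± 1.44% and 16.6 ± 2.62% (exact permutation p = 0.0179 for both, two-sided, the smallest that 5 against 3 allows; adjusted 0.143). Of the 24 tests of library measures none passed after adjustment. Those at single days of the DSS experiment could not pass, since 3 against 3 allows no p under 0.1.

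**Figure D4:**
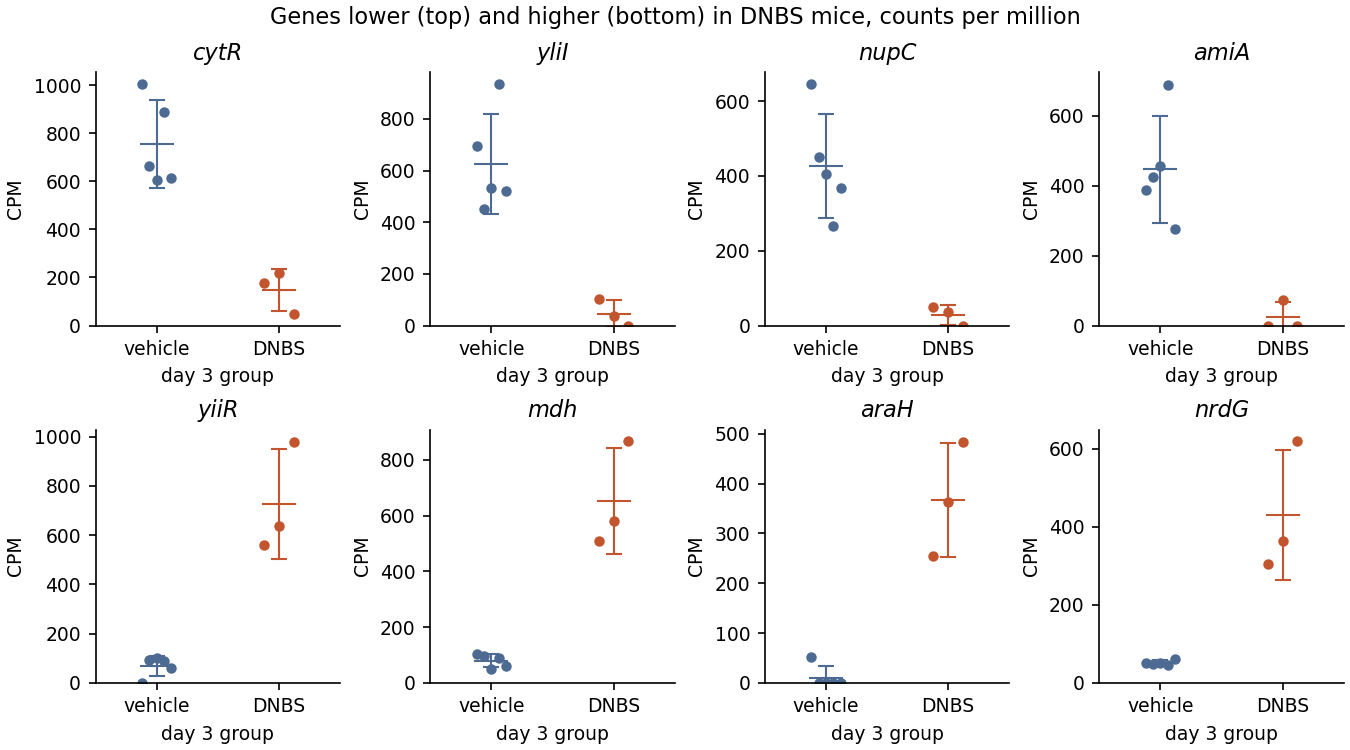
CPM of *cytR*, *yliI*, *nupC* and *amiA* (top) and *yiiR*, *mdh*, *araH* and *nrdG* (bottom) in vehicle (n = 5) and DNBS (n = 3) samples, 1 point per sample with mean and SD. The vehicle mean of *nupC* is 427 CPM and the DNBS mean 29.1 CPM, and in no gene do the groups overlap.

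The DNBS effect was set against the averaged DSS effect in a fit of 32 samples, and the difference passed in 441 of 1927 genes. *ilvC*, of branched-chain amino acid synthesis (log2 difference -2.38 ± 0.38, SE; adjusted p = 2.83e-05), *narP* (-2.75 ± 0.44), *gutM* (-6.27 ± 1.04), *agp*, a glucose phosphatase gene (-2.48 ± 0.45), and *hslJ* (-2.24 ± 0.43) had negative differences, as had *amiA*, *yliI*, *mraY*, *ynfD*, *yafN* and *yjeP*. *acs* (5.93 ± 1.19), *rne* (4.07 ± 0.88), *sucA* (2.26 ± 0.49) and *zipA* (1.65 ± 0.37) had positive ones, and *hupB* (0.85 ± 0.19), *rob*, a stress regulator (2.36 ± 0.51), *lpxB*, of lipid A synthesis (2.42 ± 0.54), *yfeS*, *ycbS*, *plsC* and *ybl117* had as well. *envC*, of cell division, passed in the same direction without a count in vehicle mice. In *gutM*, *amiA*, *yafN*, *yjeP*, *acs*, *plsC* and *envC* a group had no count, so that their fitted differences are no bounds. *ahpC* differed by -1.95 ± 0.50 (adjusted p = 0.00408), standing higher in DSS than in water mice and at 295 CPM in DNBS against 513 CPM in vehicle mice. *katG* (-0.87 ± 0.41, adjusted p = 0.116), *lacZ*, *nanA*, *tnaA*, *recA* and *hmp* did not pass.

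Of the 441 differences 147 were positive and 294 negative, or 33.3% positive, and 46.7% were positive with library size only, which moved the median over all genes from -0.27 to -0.08. Without DNBS replicate 3 the count was 164. A fit of all 33 libraries with the library number gave 355, 282 of them among the 441, and *katG* and *lacZ*, with negative differences, passed as well. In that fit too, vehicle replicate 4 and DNBS replicate 3 do not inform the DNBS effect. No gene list passed (lowest adjusted p = 0.291, nucleotide metabolism, with 5 of 23 members lower and 5 adjusted over the list alone; 0.850 with an estimated correlation). Across genes, which are not independent replicates, the 10 correlations of fold changes between the DSS days and DNBS ran from -0.17 to 0.26, with a lowest adjusted permutation p of 0.650. These permutations leave the library number out; with the number in a fit of all 33 libraries and held in place, the correlations ran from -0.11 to 0.10 (lowest adjusted permutation p = 0.970) and the permuted ones from -0.80 to 0.76. Day 5 and day 15 shared *dnaK*, *tnaA* and *yidA* among genes higher, 3 where independence gives 4.73, and day 5 and DNBS shared 22 where it gives 26.0. Day 24 and DNBS shared *nagB* among higher and *srlB* among lower genes, where independence gives 0.795 and 1.76.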

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

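Written after the result was seen were the tests of shared handling, of scaling and thinning for the lean at day 5, and of thinning for the 4 genes named with it, and the share over all tested genes set beside the nearness to later water; the other tests in this part were written before.

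In the vehicle group, the only group of at least 4 samples, 46 measures were tested for 1 sample apart, and 10 had one; chance gives about 1 in 20. That rate does not apply to *araH* and *acs*, whose 2 counts in the group lie in 1 library, so that their gap was fixed. The rate also takes samples as alike but for chance, while libraries deviate with their library number. The gap over the range was 1.0 for *araH* (replicate 1 at 51.6 CPM, the others at 0), 0.782 for *ybbA* (replicate 4 at 489, the others 155 to 228), 0.720 for *ynfD* (replicate 4 at 1601, the others 232 to 616) and 0.779 for *pepA* (replicate 4 at 600, the others 103 to 213). It was 0.772 for *recA* (replicate 5 at 3121, the others 1184 to 1625), 0.760 for *lacZ* (replicate 5 at 2356, the others 534 to 971) and 0.939 for *gutM* (replicate 5 at 839, the others 205 to 244). It was 0.849 for *ycbS* (replicate 2 at 141, the lowest of the others at 45.5), 1.0 for *acs* (replicate 2 at 46.9, the others at 0) and 0.847 for *lpxB* (replicate 3 at 752, the others 114 to 211). Vehicle replicate 5 shares its library number with replicate 3 of water and of DSS mice at day 15. In *lacZ* these stood at 1218 CPM (the other water libraries 308 and 343) and 1211 CPM (the other DSS libraries 247 and 286). In *recA* the water library was the highest of its group (2006 CPM) and the DSS library was not (1175 CPM). An effect of the number thus cannot be told apart from a sample apart in *lacZ*.

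The DSS effect differed between days in 239 genes by the edgeR test of that difference. Adjusted p was 2.71e-04 for *gatC*, 3.52e-04 for *tnaA*, *aspA*, *rrsD*, *rrsG*, *yeiH* and *lpp*, 4.78e-04 for *rnr*, 7.00e-04 for *xylH*, 7.14e-04 for *nagC*, 9.55e-04 for *clpA* and 0.00101 for *murA*. The splits given here do not take the library number into account. Of 100 splits of the samples, the real one included, 1 gave as many genes (239, the highest other 71). This excludes chance only for libraries taken as independent, and it cannot tell the groups apart from shared handling of a group. The same held for days among water mice (399, the highest other 81, 1 of 100) and for the averaged DSS effect (177, the highest other 3, 1 of 100).

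The DNBS effect differed from the averaged DSS effect in 441 genes by the test of the difference itself. The log2 difference was -2.38 for *ilvC*, -2.75 for *narP*, -6.27 for *gutM*, -5.48 for *amiA*, -4.39 for *yliI*, -4.08 for *mraY*, -4.29 for *ynfD*, -2.48 for *agp*, -2.24 for *hslJ*, -5.21 for *yafN*, -4.01 for *yjeP* and -1.95 for *ahpC*. It was 4.25 for *yfeS*, 3.22 for *ycbS*, 5.93 for *acs*, 7.79 for *envC*, 5.43 for *plsC*, 4.07 for *rne*, 2.26 for *sucA*, 2.36 for *rob*, 3.14 for *ybl117*, 0.85 for *hupB*, 1.65 for *zipA* and 2.42 for *lpxB*. Of 50 splits 1, the real one, gave as many genes (441, the highest other 130), and of the 56 splits of the DNBS experiment 1 did (501, the highest other 0). In both, chance is excluded only for libraries taken as independent, with shared handling of a group left open.

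At the single days of the DSS experiment the 10 splits of 6 samples are too few for a share under 0.05. The real splits, 1 of 10 at each day, gave 273, 136, 40 and 22 genes at days 5, 9, 15 and 24, and the highest other split gave 0 at each.

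The 3 libraries of a group shared which sparsely counted genes they held. Genes with totals of at most 150 counts correlated at a mean of 0.475 within water groups and 0.295 between them, a difference of 0.180 (0.201 without day 5), and since the labels give no inoculum or library batches, shared handling of a group cannot be told apart from the groups. With day 5 left out, DSS against water of 1 day gave a median of 40 genes (22 to 136) and pairs of water days a median of 30 (8 to 140), a ratio of 1.33, between the bounds set for colitis treatment as the source. DSS against water of another day gave 37 (0 to 285) and pairs of DSS days 104 (49 to 150), so these ranges overlap. Changes in transcription would make adjacent genes of 1 strand move together: their fold changes in DNBS correlated at 0.0828, under the 95th percentile of 1000 rotations (0.102) by less than the rotations' SD of 0.0586, a margin set after the value was seen, so this stays open. The same correlation lay above the 95th percentile at day 9 (0.121 and 0.0725), day 15 (0.0895 and 0.0794) and day 24 (0.111 and 0.0759), and not at day 5 (-0.0354). Adjacent genes on opposite strands gave 0.0950 in DNBS, 0.0627, 0.0819 and 0.115 at days 9, 15 and 24 and -0.0590 at day 5, so apart from day 9 the values for 1 strand were near or under those for opposite strands. Pairs on 1 strand at most 50 bases apart were run first, but the prediction named no distance, so the test without one decided. These close pairs gave 0.186, 0.132 and 0.236 at days 9, 15 and 24, above their 95th percentiles of 0.112, 0.112 and 0.115. They gave 0.119 in DNBS and 0.0766 at day 5, under theirs of 0.146 and 0.107.

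Of the genes called at day 5, 79.9% were higher in DSS. With library size only 37.6% were higher, so the lean may come from scaling between libraries of unequal depth. With the DSS libraries thinned to the depth of the water libraries 66.1% were higher, between the bounds set, so depth alone is open. Water libraries of day 5 standing apart stays open too: for 70.7% of called genes DSS at day 5 lay nearer to water mice of later days than water at day 5 did, but this was 65.1% of the 218 higher genes, which make the lean, and 64.0% of all tested genes. It was 92.7% of the 55 lower genes, of which 49 had water of day 5 above later water and 1 had DSS of day 5 under it. Of the 218 higher genes 107 had DSS of day 5 above later water and 75 had water of day 5 under it. These genes were picked with the same libraries of day 5, so none of these counts tells an effect of DSS apart from water of day 5 standing apart. An effect of DSS at day 5 stays open.

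*dnaK*, *tnaA*, *aspA* and *gatC* were higher in DSS at day 5. Depth of the water libraries, as fewer counts alone, is argued against, since after thinning all 4 passed in 9 of 9 draws. The 4 genes held 40 to 288 counts in water mice. Thinning draws counts at random and left the median over all genes at log2 fold changes of 0.29 to 0.35. It thus cannot speak to scaling or to libraries poor in spacers. With library size only 1 of them, *tnaA*, lost its call (log2 fold change 1.00 ± 0.17 before and 0.42 after, adjusted p = 0.0780, range over its alternatives 1.37e-07 to 0.107), and with RLE none did, so scaling as the source is open. DSS mice of day 5 lay above water mice of days 9 to 24 by a median log2 difference of 0.44 over the 4 genes (0.34 for *dnaK*, adjusted p = 0.0502), between the bounds set before, so water libraries of day 5 standing apart cannot be told apart from an effect of DSS. An effect of DSS on these genes could thus hold, as a hypothesis.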

How the results depend on the processing

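The alternatives with halved counts, thinned libraries, day 5 left out, separate DNBS libraries and the library number block were added after seeing the data; the others were planned. The genes picked by the naming rule gave 6130 values, of which 5771 stayed on their side of the threshold, 291 lost their call, 68 gained one and 0 reversed. A call in all alternatives was kept by 23 of 24 such genes for DNBS, 21 of 25 for its difference from DSS, 10 of 26 at day 5, 13 of 25 at day 9, 0 of 17 at day 15, 1 of 18 at day 24, 8 of 32 on average, 8 of 12 between days and 3 of 14 among water days. The 248 values of library measures moved by less than their spread, and the 30 of correlations by less than the SD of the permuted ones. Shallow libraries limit what could be called, as 3 counts stood for up to 615 CPM.

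At day 5, 273 genes became 160 with RLE factors, 141 with library size only, 176 with a minimum count of 10, 142 with DESeq2, 115 with limma voom, 113 after thinning and 32 with only the 6 samples of the day. At day 9, 136 became 81 with limma voom, 41 with only the 6 samples of the day and 69 with the replicate block. At day 15, 40 became 26 with a minimum count of 10, 23 with no filter, 173 with limma voom, 110 with halved counts, 183 with only the 6 samples of the day and 11 with the replicate block. At day 24, 22 became 43 with DESeq2, 112 with limma voom, 68 with halved counts and 163 with only the 6 samples of the day. The average of 177 became 93 without day 5, the 239 between days 51 with limma voom and 137 with the replicate block, and the 399 among water days 58 with limma voom and 204 without day 5. The 501 for DNBS became 285 with a minimum count of 10 and 794 with no filter, which test fewer and more genes. For the other changes the cause was not tested. The replicate block gave 214 at day 5, 25 at day 24, 133 on average and, with the 9 libraries separate, 437 for DNBS. Replicate numbers do not pair the samples of 1 day: of 16 pairs of control and treated samples with the same number, 2 correlated above 0.1 (-0.31 to 0.44), and 3 of 16 samples correlated best with their own number. The number in the library name did recur with shared deviations, over days and treatments. With the library number block day 15 gave 205 and the test between days 449; the counts of the other comparisons stayed within 1.5 times (401, 133, 24, 155, 516, 536 and 355 in the order of the report), with 12 calls of named genes lost and 11 gained. For DNBS this block takes up vehicle replicate 4 and DNBS replicate 3, each the only library with its number. DNBS gave 502 genes with its 9 libraries separate and 556 in the fit of all samples, and the difference from DSS gave 461 with 33 libraries.

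With 1 replicate left out, the counts ran from 171 to 297 at day 5, 39 to 147 at day 9, 0 to 10 at day 15, 3 to 21 at day 24, 109 to 219 on average, 132 to 277 between days, 316 to 456 among water days, 157 to 501 for DNBS and 164 to 470 for the difference from DSS.

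For the list heat shock, DSS versus water at day 5, adjusted p (0.0305) stood at 0.632 with an estimated correlation, 0.663 with RLE, 0.706 with library size only, 0.369 with a minimum count of 10, 0.863 with only the 6 samples of the day, 0.168 with the library number block and 0.727 in the thinned draw of median gene count (0.0761 to 0.881 over 9 draws, median 0.520). On average it stood at 0.270, 0.0505, 0.156 and 0.0569 with the first 4 of these, at 0.226 without day 5 and at 0.0556 with the library number block. For the list nucleotide metabolism, DSS versus water averaged over the 4 days, adjusted p (0.0409) stood at 0.270 with an estimated correlation, 0.0505 with RLE, 0.448 with a minimum count of 10, 0.0585 with no filter, 0.0816 with halved counts, 0.0514 with the replicate block, 0.118 without day 5 and 0.204 with the library number block. With fry 20 lists passed at day 5, 1 each at days 9, 15 and 24, 13 on average, 2 for DNBS and 12 for the difference, where camera passed 1, 0, 0, 0, 2, 0 and 0. At day 5, 0 lists passed under the alternatives given above for heat shock. On average 0 passed with an estimated correlation, RLE, a minimum count of 10, the library number block and without day 5, and 1 with library size only, no filter, halved counts and the replicate block. With 1 replicate left out, heat shock at day 5 ran from 0.000783 (without HC_D5 replicate 1) to 0.219 (without HC_D5 replicate 2), nucleotide metabolism on average from 0.0264 (without DSS_D9 replicate 2) to 0.235 (without HC_D5 replicate 2), and the lists that passed from 0 to 1 at day 5 and 1 to 3 on average.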

Other observations

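The values of this part were chosen after they were seen. Averaged over the 4 days, 3 of 12 measured fermentation genes were higher in DSS mice and none lower: *ldhA*, lactate dehydrogenase (log2 fold change 0.73), *pflB* (0.69) and *adhE*, which makes ethanol (0.37), with 3 adjusted over the list alone and camera adjusted p = 0.379 (0.466 with an estimated correlation). Of 15 aerobic respiration genes the cytochrome bd oxidase genes *cydA* (0.85) and *ybgT* (0.85) were higher and none lower (2 adjusted over the list alone; adjusted p = 0.891, and 0.930 with an estimated correlation); the median (0.15) and mean (0.07) were above 0 while camera pointed down. Of 13 SOS response genes *lexA*, the SOS repressor (0.77), and *recA* (0.66) were higher and *ruvA*, of Holliday junction migration (-1.68), was lower (5 and 2 adjusted over the list alone; adjusted p = 0.795, and 0.898 with an estimated correlation). Of the zinc, manganese and copper list *copA*, a copper exporter (1.18), and *zntA*, a zinc exporter (0.80), were higher and *cusB* (-1.54) was lower (2 and 1 adjusted over the list alone; adjusted p = 0.795, and 0.898 with an estimated correlation).

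In the DNBS comparison, genes of 1 transporter or 1 pathway were found on both sides. *araH* was higher and so was *araF*, the arabinose-binding protein gene (3.39), while *araG* of the same transporter was lower (-2.23). Among the *ilv* genes of branched-chain amino acid synthesis, which were not taken as 1 operon, *ilvL* (0.73), *ilvG* (2.28) and *ilvM* (3.51) were higher. *ilvB* (-1.79) and *ilvC* (-1.83) were lower. *znuA* was higher (2.56) and *znuC* lower (-1.39), both of the zinc importer. The sorbitol operon was on 1 side: *srlA* (-2.94), *srlE* (-2.52), *srlB* (-1.92) and *gutM* (-3.43) were lower, and *srlD* stood at -0.65 ± 0.70 (adjusted p = 0.486), which did not pass.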
